A study of Arabidopsis thaliana with 12 samples.

How the data were processed

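Poly(A) or total RNA selection is not stated in the labels, which give total RNA of whole Arabidopsis thaliana seedlings and a directional library kit. Seedlings were 10 days old, were grown at 22 °C under conditions the labels call LD, on medium with 3% sucrose, and were harvested at predawn (ZT 0) or postdusk (ZT 12). ZT counts hours from lights-on. The genotypes were the wild type Col-0 and tic-2, a mutant of TIME FOR COFFEE (TIC). Each of the 4 groups had 3 libraries, which the series description calls biological replicates, so p-values measure the spread between separately grown samples as far as that description goes.

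The authors deposited 1 table of FPKM values (fragments scaled by gene length and library size) with 12 columns, 1 per library, and 25729 genes. Per the submitters' processing notes, TopHat, TopHat2, edgeR and the TAIR10 genome build were used, but the notes give no versions or roles. The read counter, the filters and whether counting used strand are not given in the sources used here. Of the gene identifiers, 25453 matched the RefSeq annotation of assembly TAIR10.1, from which symbols and coordinates were taken, and 276 did not.

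Each column of the table was assigned to a group by the genotype and the ZT that its own name spells out. The description field of 6 samples disagrees with the title and characteristics of the same samples: records titled tic-2 at predawn carry the short column name of Col-0 at postdusk, and the reverse. Titles and characteristics match each other and were used for the groups. Columns were therefore not tied to single sample records, and the letters A, B and C in the column names are used only as names of libraries. CCA1 and LHY, transcripts of the morning, and TOC1, GI and ELF4, transcripts of the evening, were used to check the time in the column names. The kind of lesion in tic-2 is not given in the labels, so the level of the TIC transcript does not check the genotype labels, and genotypes below are those of the labels.

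The depth behind the values was recovered from the FPKM steps. With the summed exon length of each gene in the TAIR10.1 annotation, between 99.4% and 99.5% of the values in each library were whole reads within a tolerance of 0.05 reads. The totals used as denominators were between 19255016 and 21750334 reads per library, so 1 read in a gene with 1 kb of exons was worth between 0.046 and 0.0519 FPKM. Reads were recovered for 25314 genes (98.4%). Pairs of replicates differed by more than counting noise, with a mean chi-square per gene between 6.36 and 44.4, so no library was counted as a copy of another. Genes with near-identical copies (LHCB1 and LHCB2, RBCS, SAUR19 to SAUR24, the seed storage albumins) are uncertain as single genes, because the handling of shared reads is not given.

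Values were tested as log2(FPKM + 1), with a pseudocount of 1, in limma 3.58.1 (R 4.3.3). Genes with FPKM of at least 1 in at least 3 libraries were kept, which left 19274 genes and removed 6455. All 12 libraries entered 1 fit of group means with 8 residual degrees of freedom, moderated with a mean-variance trend (3.78 prior degrees of freedom). Contrasts were tic-2 over Col-0 at predawn, the same at postdusk, the difference between those effects (the interaction), and postdusk over predawn within each genotype. P-values were adjusted by the Benjamini-Hochberg method over the genes kept, and a gene was called at an adjusted p under 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, and ratios written as "-fold" are ratios of group mean FPKM. A stated SE belongs to the log2 fold change.

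A total of 21 gene lists with 324 genes were fixed before the data were examined: morning clock, evening clock, clock output, phytochrome signalling, PIF and targets, auxin response, cell wall loosening, gibberellin and brassinosteroid metabolism, light harvesting and rubisco, starch metabolism, sugar starvation, jasmonate, abscisic acid and cold, iron homeostasis, flavonoid and anthocyanin, salicylate defence, heat shock, flowering time, cell division, root markers and seed markers. Of these genes, 5 were not analysed here and 35 fell below the filter. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. fry was an alternative. The overlap of calls at predawn and postdusk was tested with a one-sided Fisher exact test.

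Named genes were chosen by a rule fixed before the data were examined. TIC, PHYA, CCA1, LHY, TOC1, GI, PIF4 and PIF5 were always named. For each genotype contrast the rule took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between replicates. It added up to 3 called members per list by smallest adjusted p, and for the other contrasts the 5 largest changes each way. For the time effect in Col-0 it also took the clock lists. Of the 113 genes the rule took for the genotype contrasts and the interaction, those not named one by one are counted within their lists, and which of them to print was chosen after their values were seen. Other list members are named with their values to describe a list. Transposons, pseudogenes and ribosomal RNA genes were not named.

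The test was tried on simulated data with counts drawn at the means and depths of these libraries and a set of genes changed by known folds. For the predawn contrast it recovered 50% of genes changed 1.5-fold, 95.9% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 15 false calls among 18740 genes. For the postdusk contrast the shares were 66.7%, 94%, 100% and, for 8-fold, 98.0%, with 7 false calls among 18770 genes. Every gene and group was simulated with 1 dispersion, 0.0102, the median of well-covered genes with the 4 groups averaged. The mean residual SD on the log2 scale was 0.16 in Col-0 at predawn, 0.22 in Col-0 at postdusk, 0.27 in tic-2 at predawn and 0.25 in tic-2 at postdusk, so the shares and false calls do not hold for genes or groups that vary more.

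Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-of-ratios and quantile scaling, no variance trend, array weights, fits of only the 2 groups compared, a replicate block, a log2 fold change of at least 1, and leaving out each library. After the data were seen, a fit without the pair of tic-2 libraries lettered C, limma voom on the recovered reads, and median-of-ratios rescaling of the overlap were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.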

Results

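Transcript levels were measured by RNA sequencing in whole 10-day-old Arabidopsis seedlings of the wild type Col-0 and of tic-2, a mutant of TIME FOR COFFEE (TIC), a gene that acts in the circadian clock. The series title concerns TIC, hypocotyl growth and signalling by phytochrome A, the far-red light receptor encoded by PHYA. Seedlings were harvested at predawn (ZT 0) and at postdusk (ZT 12), with 3 libraries in each of the 4 groups. Depth was between 19255016 and 21750334 reads per library. In a principal component analysis of 19274 genes, component 1 held 47.1% of the variance and separated the harvest times, and component 2 held 21.8% and separated the genotypes. Replicates correlated at 0.992 across genes in Col-0 at predawn, at 0.982 to 0.988 in Col-0 at postdusk, at 0.966 to 0.983 in tic-2 at predawn and at 0.971 to 0.99 in tic-2 at postdusk.

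**Figure D1:**
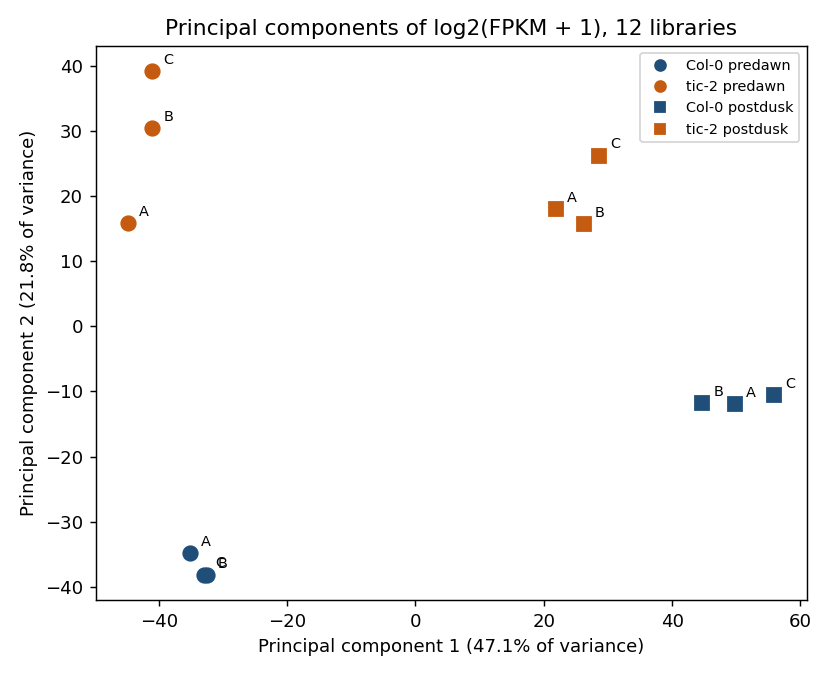
Principal components 1 and 2 of log2(FPKM + 1) in the 12 libraries, with the share of variance on each axis. Circles are predawn and squares postdusk, blue is Col-0 and orange tic-2, and letters name the libraries. The 6 predawn libraries lie between -44.8 and -32.5 on component 1, and the 6 postdusk libraries between 21.9 and 56.0.

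TIC itself (AT3G22380, chromosome 3, 7912905 to 7919707 in TAIR10.1) was not lower in the mutant. Its level was 54.9 ± 2.46 FPKM (SD, n = 3) in Col-0 and 77.5 ± 18.4 in tic-2 at predawn, and 60.9 ± 2.93 and 79.7 ± 23.1 at postdusk. Neither difference was called (limma adjusted p = 0.084 and 0.175). The predawn difference was called without the pair of tic-2 libraries lettered C (adjusted p = 0.0277), and also when single libraries were left out, tic-2 predawn A (0.0441) or tic-2 postdusk C (0.0233), and with array weights (0.00754) or a replicate block (0.0401). The log2 fold change of TIC at predawn was 0.466 in the main fit, 0.283 without the pair lettered C, 0.353 with array weights and 0.59 without tic-2 predawn A. Its adjusted p was between 0.00754 and 0.277 over the alternatives. Those C libraries held the highest TIC levels, 98.4 FPKM at predawn and 105.8 at postdusk. The time in the column names was matched by the clock transcripts in Col-0. CCA1 and LHY, which encode related MYB repressors of the morning, were at 259 ± 21.2 and 401 ± 23.2 FPKM at predawn and at 0.748 ± 0.0307 and 0.483 ± 0.0298 at postdusk. TOC1, GI and ELF4, clock components of the evening, were at 8.72 ± 0.255, 0.134 ± 0.0505 and 1.05 ± 0.313 FPKM at predawn and at 88.5 ± 4.18, 26.3 ± 4.51 and 162 ± 16.6 at postdusk.

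**Figure D2:**
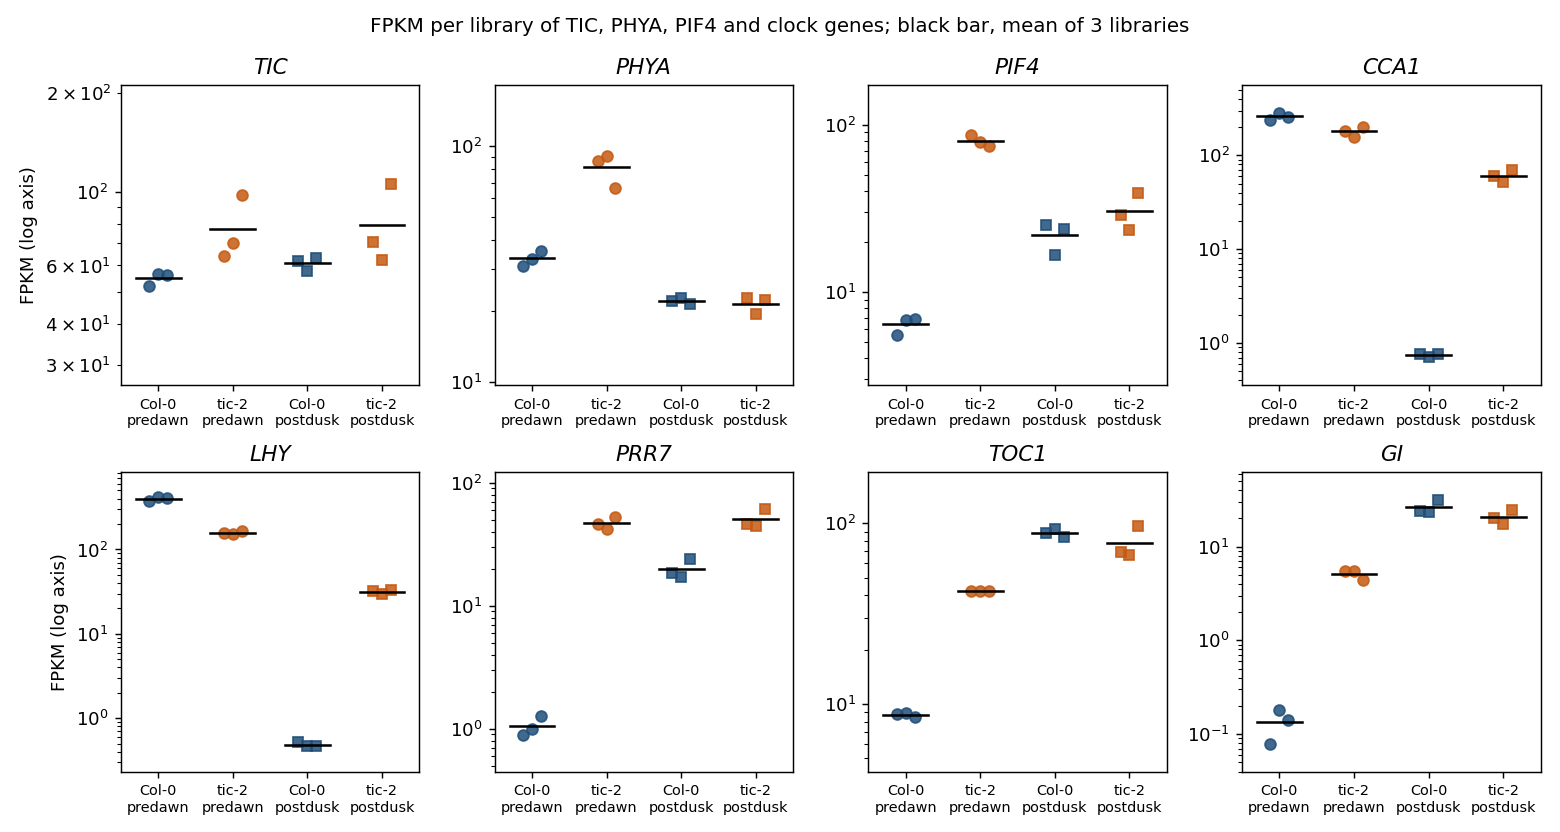
FPKM on log axes of TIC, PHYA, PIF4, CCA1, LHY, PRR7, TOC1 and GI in each of the 12 libraries, as circles at predawn and squares at postdusk, blue for Col-0 and orange for tic-2. Black bars are means of 3 libraries. PHYA and PIF4 stand apart between genotypes at predawn, at 33.4 against 81.3 FPKM and 6.42 against 79.7, while CCA1 and LHY stand far apart at postdusk.

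At predawn, the question was which transcripts differ in tic-2 at the end of the night. PHYA (AT1G09570) was 2.44-fold higher in tic-2, at 81.3 ± 13.0 FPKM against 33.4 ± 2.38 (log2 fold change 1.25, SE 0.12, adjusted p = 1.28e-05). PIF4, which encodes a bHLH factor that promotes hypocotyl elongation, was 12.4-fold higher, at 79.7 ± 6.11 against 6.42 ± 0.756 FPKM (adjusted p = 1.72e-07). Most transcripts of the evening clock list stood above Col-0, and LHY and CCA1 stood below it. limma called 5334 of 19274 genes, 2526 higher and 2808 lower in tic-2, of which 541 and 440 changed by at least 1 on the log2 scale. Groups did not overlap for 8612 genes (44.7%), where chance gives 10% for 3 against 3.

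Of the 12 evening clock genes, 10 rose and 1, ZTL, fell in tic-2 at predawn, and LKP2 was not called (camera adjusted p = 9.08e-11, and adjusted p = 0.0154 with an estimated correlation). TOC1 rose 4.84-fold to 42.2 ± 0.251 FPKM, LUX 13.7-fold to 19.0 FPKM, PRR3 23.4-fold to 10.6 ± 1.13 and GI 38.5-fold to 5.14 ± 0.628. ELF4 rose from 1.05 to 4.90 FPKM, far below its postdusk level. Of the 12 morning clock genes, 3 rose and 5 fell, and the list was not called (adjusted p = 0.724). The risers included PRR7, at 46.9 ± 5.63 against 1.05 ± 0.192 FPKM, and PRR9, at 8.58 ± 1.67 against 0.230 ± 0.179, both pseudo-response regulators. LHY fell to 158 ± 8.62 FPKM (log2 fold change -1.34, SE 0.08) and CCA1 to 180 ± 20.5 (log2 fold change -0.53, SE 0.12). RVE8 and RVE1, which encode MYB factors related to CCA1, fell as well, to 67.5 ± 3.56 from 150 ± 9.24 and to 82.5 ± 8.72 from 169 ± 21.3 FPKM.

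PIF genes and PIF targets rose together at predawn, with 13 of 19 higher and 0 lower (camera adjusted p = 1.3e-08, but adjusted p = 0.0761 with an estimated correlation). PIL1 was at 26.2 ± 7.14 against 4.19 ± 0.645 FPKM, ATHB2 at 67.5 ± 18.9 in tic-2 (log2 fold change 1.85), IAA29 at 25.8 ± 1.96 against 5.24 ± 1.66 and XTH15 at 33 ± 22.3 against 3.67 ± 0.997. PIF5 was 1.57-fold higher (adjusted p = 0.0141), a call that ended without Col-0 predawn A (0.0527) or without tic-2 predawn C (0.0547). In gibberellin and brassinosteroid metabolism 7 of 12 genes rose and 1, GA3OX1, fell (camera adjusted p = 0.000169, and adjusted p = 0.0225 with an estimated correlation). CPD, a brassinosteroid biosynthetic enzyme, was at 326 ± 16.0 against 147 ± 2.22 FPKM, and the gibberellin receptor gene GID1A at 28.6 ± 3.2 against 14.9 ± 0.521. In auxin response 8 of 20 rose and 1 fell (adjusted p = 0.0065, but adjusted p = 0.56 with an estimated correlation), with IAA7 at 228 ± 30.6 against 115 ± 9.77 FPKM. SAUR22 was at 6.8 ± 0.638 against 2.42 ± 0.74 FPKM.

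Genes that respond to carbon shortage were higher in tic-2 at predawn, with 6 of 8 in the sugar starvation list (camera adjusted p = 0.00136, but adjusted p = 0.423 with an estimated correlation). DIN6, an asparagine synthetase, was at 359 ± 60.0 against 48.8 ± 18.6 FPKM, and DIN1 at 433 ± 250 against 44.5 ± 16.0. In starch metabolism 6 rose and 5 fell of 19, and the list was not called (adjusted p = 0.413). BAM3 (AT4G17090), the plastid beta-amylase of night-time starch breakdown, fell to 32.1 ± 12.3 from 239 ± 24.4 FPKM, and ISA3, a debranching enzyme, rose to 18.9 ± 4.01 from 5.07 ± 0.619. In the flavonoid and anthocyanin list 9 of 15 fell and 0 rose (adjusted p = 0.00135, but adjusted p = 0.649 with an estimated correlation). DFR was at 1.97 ± 0.538 against 12.7 ± 3.3 FPKM and LDOX at 1.86 ± 0.752 against 9.81 ± 1.26. The acyltransferase gene 5MAT was at 0.408 ± 0.0814 against 2.6 ± 0.733 FPKM, and its call ended with a pseudocount of 5 (adjusted p = 0.0573). In abscisic acid and cold response 8 of 18 rose and 1 fell (adjusted p = 0.00136, but adjusted p = 0.49 with an estimated correlation), with COR47 at 170 ± 34.4 against 28.3 ± 2.32 FPKM. In iron homeostasis 5 of 16 rose and 1 fell (adjusted p = 0.0111, but adjusted p = 0.502 with an estimated correlation), and the ferritin gene FER1 was at 458 ± 80.0 against 147 ± 8.01 FPKM.

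In phytochrome signalling, 6 of 20 genes rose and 6 fell at predawn, and the list was not called (camera adjusted p = 0.99). Beside PHYA, its nuclear import factors FHY1 and FHL rose (log2 fold changes 1.04 and 1.06). HYH, a homologue of the light-signalling factor HY5, fell to 22.4 ± 5.89 from 96.5 ± 5.54 FPKM, and SPA3, a repressor of light signalling, to 17.0 ± 2.83 from 49.6 ± 4.01. The other lists not called at predawn, with the genes that rose and fell, were clock output (3 and 2 of 8), cell wall loosening (3 and 1 of 13), light harvesting and rubisco (5 and 7 of 21), jasmonate (6 and 1 of 24), salicylate defence (1 and 0 of 8), heat shock (0 and 0 of 6), flowering time (1 and 1 of 6), cell division (2 and 1 of 11), root markers (0 and 0 of 10) and seed markers (3 and 0 of 11). In cell division, CYCD3;1 rose to 38.5 ± 3.89 from 24.0 ± 1.23 FPKM, TSO2 fell to 19.1 ± 0.0866 from 26.2 ± 2.45, and CDKB2;1 rose to 12.4 ± 1.15 from 9.1 ± 1.01. The CDKB2;1 call ended without Col-0 predawn C (adjusted p = 0.108), tic-2 predawn A (0.0671) or tic-2 predawn C (0.0626). In salicylate defence, CBP60G was at 2.67 ± 0.289 FPKM in tic-2 (log2 fold change 0.89), a call that ended with a pseudocount of 5 (adjusted p = 0.1) and without tic-2 predawn B (0.0502). In seed markers, the call of SESA4 (adjusted p = 0.0196) ended without Col-0 predawn B (0.0503) or C (0.0792) or tic-2 predawn A (0.0651), or with a pseudocount of 0.1 (0.0798). Adjusted over the list alone, 10 evening clock, 16 PIF, 8 gibberellin and brassinosteroid, 9 auxin, 6 sugar starvation, 9 abscisic acid and cold and 6 iron genes rose, and 9 flavonoid, 2 auxin, 2 iron, 1 evening clock, 1 gibberellin and brassinosteroid and 1 abscisic acid and cold genes fell.

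The largest rises at predawn that no list held were AT1G75945, AT2G15880, a leucine-rich repeat protein gene (139 ± 59.3 against 2.06 ± 0.499 FPKM), COR413IM1, a cold-regulated plastid membrane protein gene (280 ± 9.31 against 8.04 ± 2.01), CCL (982 ± 54.7 against 48.5 ± 2.83), MEE14 (152 FPKM against 7.08), AT3G62550 (152 ± 8.49 against 8.84 ± 0.866) and AT2G33830, a dormancy and auxin associated gene (308 ± 40.6 against 20.6 ± 3.63). The largest falls were QQS, a regulator of starch content (0.740 ± 0.141 against 44.2 ± 3.19), AT3G05945 (3.1 ± 0.757 against 74.7 ± 7.18), SQP1 (1.28 ± 0.183 against 41.1 ± 5.53), AT3G28270 (1.77 ± 0.904 against 44.8 ± 7.14), the thionin gene THI2.2 (0.402 ± 0.181 against 21.2 ± 0.515), AT2G15020 (4.12 ± 1.27 against 76.1 ± 4.61), AT1G65490 (5.17 ± 1.45 against 84.8 ± 9.42) and AT5G24240 (0.0809 ± 0.0182 against 13.2 ± 0.346).

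**Figure D3:**
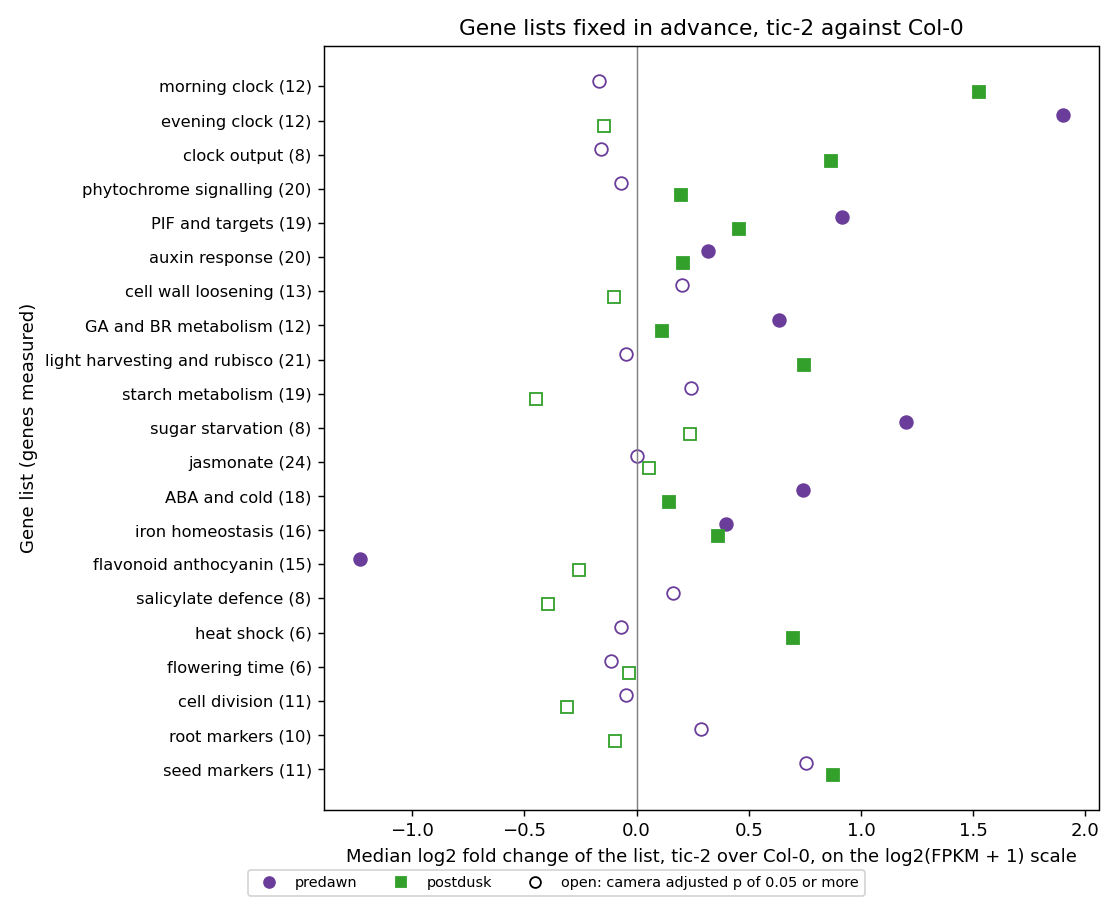
Median log2 fold change, tic-2 over Col-0, on the log2(FPKM + 1) scale of each of the 21 gene lists, at predawn (purple circles) and postdusk (green squares), with the number of genes measured in parentheses. Filled symbols have a camera adjusted p under 0.05 at the preset correlation. The evening clock list lies at 1.90 at predawn and -0.14 at postdusk, and the morning clock list at -0.17 and 1.53.

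At postdusk, the same comparison was made at the end of the day. Most morning clock transcripts were higher in tic-2. CCA1 was at 60.6 ± 8.71 FPKM in tic-2 against 0.748 ± 0.0307 in Col-0 (81.1-fold, adjusted p = 1.85e-10), and LHY at 31.5 ± 1.82 against 0.483 ± 0.0298 (65.2-fold, adjusted p = 2.35e-11). PHYA was at 21.4 ± 1.82 against 22.0 ± 0.572 FPKM and was not called (log2 fold change -0.04, SE 0.12, adjusted p = 0.833). PIF4, at 30.5 ± 7.92 against 21.8 ± 4.59, was not called either (adjusted p = 0.0794), but was called without tic-2 postdusk B (0.0284), after median-of-ratios rescaling (0.0485) and with array weights (0.023), in a range up to 0.272 over the alternatives. limma called 5686 genes, 1872 higher and 3814 lower, of which 359 and 256 changed by at least 1 on the log2 scale. Groups did not overlap for 9015 genes (46.8%), against 10% by chance.

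The split between higher and lower calls at postdusk rested on the scaling. The median log2 fold change of all genes was -0.12 as deposited and -0.01 after median-of-ratios rescaling. Higher calls made up 32.9% of the calls as deposited, 57.4% after that rescaling and 50.7% after quantile normalization. Relative to that shift, the genes named below kept their direction, except PHYA, which was not called.

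At postdusk, 11 of the 12 morning clock genes were higher in tic-2 and 0 lower, and RVE6 was not called (camera adjusted p = 1.13e-19, and adjusted p = 0.0166 with an estimated correlation). RVE1 was at 33.9 ± 12.1 against 1.81 ± 0.425 FPKM and RVE8 at 22.7 ± 2.33 against 1.74 ± 0.443. The evening clock list was not called (adjusted p = 0.945), with 1 higher and 2 lower of 12. FKF1, a blue-light receptor of the photoperiod pathway, fell to 8.95 ± 1.67 from 31.1 ± 4.15 FPKM, ELF4 fell to 91.8 ± 27.1 from 162 ± 16.6, and BOA, a homologue of LUX, rose to 12.6 ± 0.807 from 6.65 ± 0.493. TOC1 was at 77.7 ± 16.5 against 88.5 ± 4.18 FPKM and GI at 20.6 ± 3.68 against 26.3 ± 4.51, neither called, but both were called as lower without tic-2 postdusk C (adjusted p = 0.00502 and 0.0342), without both C libraries (0.00298 and 0.0214) and with array weights (0.0013 and 0.00415). In clock output 5 of 8 rose and 1 fell (adjusted p = 0.000223, but adjusted p = 0.0871 with an estimated correlation), with the flowering repressor CDF1 at 30.5 ± 2.78 against 5.99 ± 1.88 FPKM and catalase CAT2 at 798 ± 152 against 222 ± 3.03.

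Light-harvesting genes were higher in tic-2 at postdusk, with 13 of 21 in the light harvesting and rubisco list and 0 lower (camera adjusted p = 1.05e-12, but adjusted p = 0.0911 with an estimated correlation). LHCB1.1 was at 332 ± 7.32 against 66.5 ± 9.1 FPKM, LHCB2.1 at 336 ± 44.0 against 73.6 ± 11.5 and LHCB2.3 at 65.3 ± 8.14 against 13.7 ± 3.81. LHCB1 and LHCB2 genes have near-identical copies. LHCA4 was at 1802 ± 86.5 against 704 ± 105 FPKM. None of the 4 rubisco small subunit genes was called at postdusk. In the PIF list 7 of 19 rose and 0 fell (adjusted p = 0.000113, but adjusted p = 0.198 with an estimated correlation), with PIF5 at 60.2 ± 12.1 against 27.8 ± 5.17 FPKM, ATHB2 at 19.2 ± 5.1 against 10.3 ± 0.532 and ATHB4 at 3.84 ± 0.412 against 1.68 ± 0.0897. In phytochrome signalling 6 of 20 rose and 1, PHYD, fell (adjusted p = 0.00414, but adjusted p = 0.395 with an estimated correlation). HYH was at 27.9 ± 5.35 against 11 ± 1.43 FPKM and SPA3 at 29.4 ± 3.43 against 17.9 ± 1.1 FPKM, both higher here and lower at predawn.

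Of the other lists called at postdusk, gibberellin and brassinosteroid metabolism had 5 of 12 higher and 0 lower (camera adjusted p = 0.0106, but adjusted p = 0.0911 with an estimated correlation). Auxin response had 4 higher and 1 lower of 20 (adjusted p = 0.0056, but adjusted p = 0.395 with an estimated correlation), and abscisic acid and cold had 5 higher and 3 lower of 18 (adjusted p = 0.0375, but adjusted p = 0.493 with an estimated correlation). Iron homeostasis had 3 of 16 higher, FER1, FER4 and PYE, and 0 lower (adjusted p = 0.000825, but adjusted p = 0.237 with an estimated correlation), with FER1 at 856 ± 93.1 against 266 ± 45.4 FPKM. Heat shock had 2 of 6 higher (adjusted p = 0.0375, but adjusted p = 0.437 with an estimated correlation). Without the tic-2 libraries lettered C its adjusted p was 0.265, and its median log2 fold change went from 0.70 to 0.26. HSP70-4, at 73.6 ± 50.3 against 29.8 ± 7.03 FPKM, was no longer called without Col-0 postdusk A (adjusted p = 0.0549) or B (0.106) or in a fit of only the 2 groups (0.101), and its log2 fold change went from 1.1 to 0.59 without tic-2 postdusk C. The abscisic acid and cold list lost its call after median-of-ratios rescaling (adjusted p = 0.138) and without the C libraries (0.0649), and the heat shock list after rescaling (0.12). HSP101, at 6.32 ± 3.19 against 3.25 ± 1.02 FPKM, had an adjusted p of 0.0444, which rose above 0.05 under 12 of 24 alternatives (highest 0.138), among them leaving out any library of Col-0 at predawn (highest 0.0605), Col-0 postdusk B (0.138) or C (0.115), tic-2 predawn B (0.058) or tic-2 postdusk C (0.118). The HSP101 log2 fold change went from 0.725 to 0.39 without tic-2 postdusk C. In auxin response, IAA5 was at 1.53 ± 0.532 against 0.385 ± 0.0671 FPKM.

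Starch genes went both ways at postdusk, with 5 higher and 9 lower of 19 and no call for the list (adjusted p = 0.644). BAM9 and GBSS1, a starch synthase, were higher, at 76.1 ± 7.96 against 19.2 ± 1.37 and 155 ± 23.3 against 46.4 ± 20.8 FPKM. DPE1, a disproportionating enzyme, was lower, at 19.4 ± 1.11 against 46.2 ± 1.84. In the jasmonate list 5 rose and 3 fell of 24, and it was not called, with JAZ9 at 151 ± 57.1 against 45.1 ± 2.44 FPKM, LOX2 at 309 ± 85 against 631 ± 32.3 and CORI3 at 37.9 ± 3.48 against 112 ± 14.4. In salicylate defence 1 rose and 2 fell of 8, with WRKY70 at 15.2 ± 3.87 against 82.2 ± 49.2 FPKM. In flavonoid and anthocyanin synthesis, the glycosyltransferase gene UF3GT was at 9.31 ± 3.56 against 21.6 ± 8.61 FPKM, a call that ended without Col-0 postdusk B (adjusted p = 0.0857) or C (0.0889) or tic-2 postdusk A (0.087) or C (0.0651), without both C libraries (0.07) or in a fit of only the 2 groups (0.0603). In cell division, TSO2 fell to 17.9 ± 2.21 from 32.5 ± 1.99 FPKM. CYCB1;2 was at 5.57 ± 1.02 against 7.76 ± 0.399 FPKM, and its call ended after median-of-ratios rescaling (0.0854) or quantile normalization (0.0837) and without Col-0 postdusk A (0.0535) or C (0.0603) or tic-2 postdusk A (0.0673) or B (0.0579). The CYCD3;1 call (0.0206, at 35.2 ± 3.44 against 26.9 ± 2.58 FPKM) ended without Col-0 postdusk A (0.0828) or B (0.0532) or tic-2 postdusk B (0.0663). The remaining lists not called, with the genes that rose and fell, were sugar starvation (0 and 0 of 8), cell wall loosening (4 and 1 of 13), flavonoid and anthocyanin (0 and 1 of 15), flowering time (1 and 2 of 6), cell division (1 and 2 of 11) and root markers (0 and 0 of 10). Adjusted over the list alone, 11 morning clock, 16 light-harvesting and rubisco, 8 PIF, 8 phytochrome, 5 clock output, 5 gibberellin and brassinosteroid, 4 auxin, 6 abscisic acid and cold, 3 iron, 2 heat shock and 6 seed genes rose, and 3 abscisic acid and cold, 1 clock output, 1 phytochrome and 1 auxin genes fell.

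Seed storage transcripts were higher in tic-2 at postdusk, with 5 of the 11 seed markers called, all higher (camera adjusted p = 0.00286, but adjusted p = 0.395 with an estimated correlation). SESA3, a seed storage albumin, was at 41.2 ± 21.6 FPKM against 0.305 ± 0.166, and SESA1 at 60.1 ± 30.3 against 2.83 ± 1.53. CRA1, an abundant cruciferin, was at 64.4 ± 12.8 against 102 ± 46.3 FPKM and was not called. Replicates varied widely for these genes, also in Col-0, where SESA1 ranged between 6.96 and 65.2 FPKM at predawn.

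Some large changes were found at both times. AT1G75945 was at 27.2 ± 4.41 against 1.12 ± 0.649 FPKM at postdusk and at 30.6 ± 7.07 against 1.14 ± 0.520 at predawn. QQS was at 0.757 ± 0.141 against 26.6 ± 4.11 at postdusk, AT3G05945 at 0.793 ± 0.366 against 35.7 ± 8.98 and AT5G24240 at 0.0399 ± 0.0025 against 15.3 ± 1.58. AT3G11960 was at 0.0901 ± 0.0354 against 13.7 ± 0.452 at postdusk and at 0.126 ± 0.0349 against 12.6 ± 1.5 at predawn. Other large falls at postdusk were ESM1, a modifier of glucosinolate breakdown (31.0 ± 6.03 against 252 ± 30.5), the peroxidase gene AT5G64110 (7.36 ± 1.05 against 65.7 ± 11.4), PCC1 (0.750 ± 0.794 against 19.0 ± 6.98) and AT3G22235 (1.82 ± 0.632 against 39.2 ± 12.9). Large rises included NDA1, an alternative NAD(P)H dehydrogenase gene (31.7 ± 3.46 against 2.38 ± 0.222), and the protease gene AT2G27420 (25.1 FPKM against 1.68).

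Calls at predawn and postdusk overlapped in the same direction for 1682 genes. Of these, 719 were higher at both times, where independent lists would share 245 (odds ratio 5.38, one-sided Fisher exact p = 6.59e-192), and 963 were lower at both, where 556 would be shared (odds ratio 2.49, p = 1.24e-86). Another 664 genes were called in opposite directions. Genes are not independent replicates, so these p-values describe the lists. After median-of-ratios rescaling, 1482 genes were shared in the same direction. The split of the postdusk calls rested on the scaling, so the split into 719 and 963 may move with it. With a log2 fold change of at least 1 required at both times, 145 genes were shared in the same direction and 71 in opposite directions. For opposite directions no expected number was computed, so whether those genes also exceed what independent lists share was not tested. Both contrasts take the spread of each gene from the same fit, which can place calls on the same genes.

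The interaction tested whether the genotype effect differed between the times. It did for LHY, CCA1, PHYA, PIF4, TOC1 and GI. The effect on LHY and CCA1 was larger at postdusk (interaction log2 5.79, SE 0.11, and 5.66, SE 0.17), and the effect on PHYA, PIF4, TOC1 and GI was larger at predawn (-1.29, SE 0.16, -2.99, SE 0.26, -2.36, SE 0.17, and -2.77, SE 0.20). ATHB4 (-0.31, adjusted p = 0.233) and IAA7 (-0.04, adjusted p = 0.919) showed no called difference, nor did PIF5 and TIC (0.46, SE 0.23, adjusted p = 0.227, and -0.12, SE 0.26, adjusted p = 0.815), although PIF5 did with array weights (0.0189). The largest positive values were AT2G15020 (6.75), LHY, CCA1, SQP1 (5.29) and NDA1 (5.17), and the largest negative values AT2G33830 (-5.09), AT2G15880 (-4.99), CCL (-4.85), MEE14 (-4.79) and AT3G62550 (-4.34). In all, 3060 genes were called, 1404 positive and 1656 negative. The median of all genes was -0.11, and the share of positive calls went from 45.9% to 60.2% after median-of-ratios rescaling and 57.8% after quantile normalization.

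Among the lists, the interaction was positive for morning clock (7 positive and 2 negative of 12, camera adjusted p = 7.18e-09, but adjusted p = 0.0988 with an estimated correlation), light harvesting and rubisco (11 of 21, adjusted p = 9.98e-10, but adjusted p = 0.191 with an estimated correlation) and flavonoid and anthocyanin (1 of 15, adjusted p = 0.00526, but adjusted p = 0.639 with an estimated correlation). It was negative for evening clock (10 negative and 1 positive of 12, adjusted p = 1.21e-10, and adjusted p = 0.016 with an estimated correlation) and PIF and targets (6 of 19, adjusted p = 0.021, but adjusted p = 0.581 with an estimated correlation). The PIF list was not called without the C libraries (adjusted p = 0.0889). The other 16 lists were not called for the interaction by camera. Adjusted over the list alone, the interaction was positive for 7 morning clock, 15 light-harvesting and rubisco, 1 flavonoid, 1 evening clock and 1 PIF genes, and negative for 10 evening clock, 7 PIF and 2 morning clock genes.

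In Col-0, the comparison of postdusk with predawn gave the wild-type daily change. ELF4 was 155-fold higher at postdusk, GI 197-fold, PRR3 62.6-fold, PRR5 44.5-fold, LUX 18.7-fold, PRR7 18.9-fold, TOC1 10.2-fold, BOA 8.24-fold and ELF3 2.69-fold. FKF1 was at 31.1 ± 4.15 FPKM at postdusk and 0.039 ± 0.0143 at predawn. LHY, CCA1, RVE1, LNK2, RVE8, RVE4, RVE2, RVE7 and ZTL fell, with log2 fold changes of -8.08, -7.21, -5.92, -5.80, -5.79, -3.28, -2.11, -0.96 and -0.35. PRR9, RVE6, LNK1 and LKP2 were not called, at log2 fold changes of 0.23, -0.20, -0.31 and -0.18. CHE (0.48, adjusted p = 0.0518) was not called, but was when Col-0 postdusk B (0.0217) or tic-2 postdusk C (0.014) was left out and under 5 other alternatives, with adjusted p between 0.00463 and 0.203 over all of them. RVE6 was called after quantile normalization (0.0448). Outside the clock lists, AT5G23240, AOC2, AT1G07135 and AT1G07050 rose by 5.77, 5.13, 5.12 and 5.08 on the log2 scale, and LHCB1.1 fell by 5.97. PIF4 rose by 1.60, and PHYA and PIF5 fell by 0.58 and 1.26. limma called 7142 genes, 4366 higher and 2776 lower at postdusk. The share of higher calls, 61.1%, was 51.8% after median-of-ratios rescaling and 50.1% after quantile normalization.

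In tic-2, the same comparison called 7304 genes, 3574 higher and 3730 lower at postdusk. Both counts use 1 spread pooled over the 4 groups, although the mean residual SD was larger in tic-2. Fits of only the 2 groups compared called 8961 genes in Col-0 and 5043 in tic-2. Groups did not overlap for 57.6% of genes in Col-0 and 44.3% in tic-2. The counts of 7142 and 7304 therefore do not show a daily change of equal extent. LHY and CCA1 fell by 2.29 and 1.55 on the log2 scale, less than in Col-0, and TOC1 and GI rose by 0.85 and 1.81, also less. PHYA fell by 1.87, PIF4 by 1.39 and PIF5 by 0.80, so PIF4 changed in the direction opposite to Col-0. The largest rises were SQP1 (5.07), AT3G28270 (4.35), AT2G27420 (4.33), DFR (4.31) and cPT4 (4.19), and the largest falls LHCB1.4 (-5.10), DIN6 (-4.99), DIN1 (-3.68), LHCB1.1 (-3.62) and IAA29 (-3.39). Both genotypes called 4241 genes, 3817 of them in the same direction.

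The predawn genotype effect was set against the time effect in Col-0 across 19274 genes, which are not independent replicates. The covariance of the log2 fold changes was 0.0898 (Pearson r = 0.26, Spearman rho = 0.096). The contrasts share the Col-0 predawn libraries, which alone gives a covariance. In 100 simulations of unchanged groups it was 0.0174 (r = 0.50), with the residual SD of each gene pooled over the 4 groups. Col-0 at predawn had the smallest mean residual SD, 0.16 against 0.22 to 0.27 in the other groups. The simulated values are therefore too high for the libraries that are shared. The excess covariance over the simulated value was 0.0723.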

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

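The tests of seed material, the libraries lettered C, mixing, the harvest hour and the splits without the average genotype effect were chosen after the results were seen, the criterion for the counts of other splits was written after those counts had been seen, and the linked segment was tested on a pattern already seen.

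The genotype effect differed between predawn and postdusk for 3060 of 19274 genes (15.9%) by the interaction term in limma. Among the 113 genes taken from the genotype and interaction contrasts it differed for 71. That share is raised by the rule, which took genes with large effects. Positive interaction log2 values mean that tic-2 over Col-0 was larger at postdusk. In the clock these were LHY 5.79, CCA1 5.66, RVE1 4.62 and RVE8 4.25 on the positive side, and FKF1 -3.35, PRR7 -3.23, PRR3 -3.14, LUX -3.04, GI -2.77, ELF4 -2.38, TOC1 -2.36, BOA -1.84 and PRR9 -1.30 on the negative side. In clock output and light signalling they were HYH 3.35, CAT2 3.27, COL2 2.75, CDF1 2.71, SPA3 2.18, CDF2 1.88, CAT3 -1.87 and PHYA -1.29. Among PIF, auxin, hormone and cell wall genes they were EXPA8 1.36, IAA14 1.03, EXPA1 0.97, CPD -0.63, GID1A -0.93, SAUR22 -1.03, ATHB2 -1.04, PIL1 -1.77, IAA29 -2.22, PIF4 -2.99 and XTH15 -3.16.

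For starch, sugar and photosynthesis genes the interaction log2 values were BAM9 4.07, BAM3 3.08, GBSS1 3.00, LHCB2.3 2.76, LHCB2.1 2.69, LHCB1.1 2.36, RBCS1B 1.43, DPE1 -1.63, DIN6 -2.03, ISA3 -2.15 and DIN1 -2.94. For stress, defence, iron and pigment genes they were HAB1 2.15, JAZ9 1.76, DFR 1.69, THI2.2 1.17, PAD4 0.57, ERD14 -0.51, FER3 -0.99, ESM1 -1.09, CORI3 -1.17, COR47 -1.41, CBP60G -2.33, COR15B -2.89 and COR413IM1 -3.44. For the other genes with large changes they were AT2G15020 6.75, SQP1 5.29, NDA1 5.17, AT2G27420 5.07, AT3G28270 4.77, AT1G65490 3.2, QQS 0.73, AT5G64110 -1.08, PCC1 -3.75, AT3G22235 -3.93, AT3G62550 -4.34, MEE14 -4.79, CCL -4.85, AT2G15880 -4.99 and AT2G33830 -5.09. In tic-2, QQS (0.740 FPKM at predawn and 0.757 at postdusk) and THI2.2 (0.402 and 0.307) were near the floor at both times. Their interaction values therefore mostly follow the daily change in Col-0, from 44.2 to 26.6 and from 21.2 to 8.36 FPKM. The list medians were 1.78 for morning clock, 0.79 for light harvesting and rubisco, 0.54 for flavonoid and anthocyanin, -0.42 for PIF and targets and -2.37 for evening clock.

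Most evening clock genes were higher in tic-2 at predawn, and the first technical explanation tested was postdusk RNA mixed into the tic-2 predawn libraries. A mixture needs 1 share for every gene. The share was computed for 116 genes at least 8-fold higher at postdusk in Col-0. Col-0 at predawn was taken as the base and Col-0 at postdusk as the RNA mixed in. The implied share had a median of 7.7% and quartiles of 0.8% and 23.0%. For 65.5% of the genes the interval of the share excluded that median, with 41.9% for TOC1 against 2.4% for ELF4. This argues against mixing with Col-0 postdusk RNA as the whole cause. Postdusk RNA of tic-2 was not tried as the source, and genotype effects on these genes would spread the shares as well. A harvest of tic-2 at another hour than Col-0 cannot be told apart from an altered clock phase in the mutant, because only 2 hours per genotype were sampled. The excess covariance with the Col-0 time effect (0.0723) goes with both.

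Seed storage albumins and CRU2 were higher in tic-2, with 5 of 5 called at postdusk and 3 at predawn. The 6 other seed markers had a median log2 fold change of -0.36 at postdusk and 0.02 at predawn. These values do not decide whether seed material was present in the samples, because the 6 are the markers that were not called at postdusk. Outside the list, the oleosin gene OLEO4 (1.42 at predawn and 1.3 at postdusk) and AT1G03890, a neighbour of CRU2 (2.12 and 1.57), were higher too. Both are among the genes changed by at least 1 on the log2 scale in the same direction at both times. Their rise is therefore not separate evidence of seed material. Seed material and a genotype effect on these genes cannot be told apart here. The libraries lettered C did not carry the pattern, since 4 of the 5 genes were still called at postdusk without them. Replicates varied widely.

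A total of 145 genes changed by at least 1 on the log2 scale in the same direction at both times, among them QQS, AT5G24240, AT3G11960 and AT1G75945. A chromosome segment linked to TIC that differs from Col-0 may produce such changes, and these would then gather near TIC. Within 2 Mb of TIC, 3 of 746 genes tested were so changed against 142 of 18528 elsewhere (odds ratio 0.523, 95% interval 0.106 to 1.57, one-sided Fisher exact p = 0.923). For genes changed at both times, the interval argues against a 2-fold or greater enrichment near TIC. It does not cover genes changed at 1 time, and it does not tell whether the 3 genes near TIC carry a linked difference. These were BGLU19, AT3G21380 and DELTA-VPE, all lower in tic-2 at both times. BGLU19 and AT3G21380 start at 7524054 and 7528181 on chromosome 3. PCC1 and AT3G22235, which were lower at postdusk and low in both genotypes at predawn, start at 7845823 and 7854419 on chromosome 3, close to TIC (7912905), and a linked difference at these genes stays open. Changes elsewhere in the genome that came with the tic-2 line, and effects of the mutation itself, were not tested apart.

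For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the 1 that gave the most calls each time: 5334 against at most 0 in the other splits at predawn, 5686 against 1 at postdusk, 7142 against 0 for time in Col-0 and 7304 against 5 for time in tic-2. The other splits mix the 2 groups compared, so the real effect enters their residuals and lowers their counts. Those low counts are not the level of calls that chance gives. For the interaction, 2 of 100 splits drawn gave as many calls as the real 3060, the real one included. The other was the split with genotypes exchanged at 1 time, which measures the average genotype effect and called 7572 genes, a structure of the samples. The next highest called 1721. The genotype effect shared by both times enters the residuals of the other splits and lowers their counts. With that average effect removed from each gene first, 1 of the 100 splits gave as many, the real one, and the highest other called 12 genes. The interaction itself still enters those residuals and lowers those counts as well. Neither count therefore measures how many calls chance gives, and chance was not excluded by them.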

How the results depend on the processing

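The fit without the pair of tic-2 libraries lettered C, limma voom on recovered reads and rescaling of the overlap were chosen after the data were seen. Counts of called genes stayed within 1.5 times under the pseudocounts, filters, scalings, no variance trend and fits of only the groups compared. limma voom called 5324 genes at predawn, 5846 at postdusk, 2966 for the interaction, 7134 for time in Col-0 and 7363 for time in tic-2. Array weights raised the counts to 9532 at predawn, 10443 at postdusk, 7954 for the interaction and 12164 for time in tic-2, with weights from 0.228 for tic-2 postdusk C to 7.55 for tic-2 postdusk A. The cause was not tested. A log2 fold change of at least 1 left 981, 615 and 1180 genes for predawn, postdusk and the interaction, 1590 and 1437 for time in Col-0 and tic-2, and 145 in the overlap, by construction. Leaving out 1 library gave 3802 to 6096 genes at predawn, 3874 to 6614 at postdusk, 2201 to 3603 for the interaction, 5647 to 7848 for time in Col-0 and 6044 to 7339 for time in tic-2. Without the C libraries the counts were 5946, 6548, 4440, 8921 and 7504, and the overlap 1799.

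With an estimated correlation, 2 of 8 lists were still called at predawn, 1 of 11 at postdusk and 1 of 5 for the interaction, and fry called 11 lists for the interaction, 9 at predawn and 9 at postdusk. At predawn these held all 8 lists that camera called, and cell wall loosening as higher (adjusted p = 0.0327). At postdusk fry shared 6 of 11 and lost phytochrome signalling (adjusted p = 0.0707), auxin response (0.11), abscisic acid and cold (0.263), heat shock (0.191) and seed markers (0.0553). It gained starch metabolism (0.0433), salicylate defence (0.0363) and cell division (0.0228), all as lower. For the interaction it shared 4 of 5 and lost flavonoid and anthocyanin (0.324). It gained clock output as positive (0.000622). As negative it gained gibberellin and brassinosteroid metabolism (0.000588), starch metabolism (0.0454), sugar starvation (0.0454), abscisic acid and cold (0.0429), salicylate defence (0.0303) and cell division (0.0429). The excess covariance was between 0.0722 and 0.101 under 3 alternatives.

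Values that changed sign were all short of the threshold. PHYA at postdusk was 0.085 after median-of-ratios rescaling, 0.047 after quantile normalization and 0.033 with array weights, and between -0.078 and 0.032 when 1 library was left out. The interaction of TIC ranged from -0.34 to 0.064, and its time effect in tic-2 from -0.194 to 0.21, when 1 library was left out, and the latter was -0.012 without the C libraries. Among the values of named genes, at least 205 kept direction and side of the threshold under each alternative, except that fits of only the 2 groups, which give no interaction, kept 192, with 3 calls lost and 1 gained.

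A replicate block on the library letter gave 5093 genes at predawn, 5324 at postdusk, 2789 for the interaction, 6839 and 7048 for time in Col-0 and tic-2, and 1524 in the overlap. Same-letter residuals correlated between -0.327 and 0.206 over 18 pairs. Of the libraries, 0 were closest to their own letter in every group, and 4 were closest to it on average. The residuals thus gave no sign that the letters pair the samples, which does not exclude a weak pairing. At this depth, 6455 genes below the filter were not tested, and in data simulated with 1 dispersion for all genes 50% of 1.5-fold changes at predawn and 66.7% at postdusk were recovered.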

Other observations

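The tests of gene families in this part were chosen after the data were seen, and their word patterns were revised after a first look. Families were picked by words in the RefSeq product names, 21 families in all, and tested with camera and Benjamini-Hochberg adjustment. Over all 19274 genes tested, 27.7% were called at predawn (2526 higher and 2808 lower) and 29.5% at postdusk (1872 higher and 3814 lower). After median-of-ratios rescaling, 4370 genes were called at postdusk, 57.4% of them higher. At postdusk, 25 of 34 proteasome genes were lower in tic-2 and 0 higher, with a median log2 fold change of -0.36 (adjusted p = 7.26e-07, but 0.332 with an estimated correlation). After median-of-ratios rescaling, 13 were lower and the median was -0.24. Genes with "ribosomal protein" in their names were also lower at postdusk, with 100 of 308 lower and 2 higher (median -0.37, adjusted p = 8.86e-08, but 0.64 with an estimated correlation), and 40 were lower after rescaling. At predawn 29 of them were lower and 3 higher (median -0.14, adjusted p = 0.00759, but 0.93 with an estimated correlation), a smaller share called than among all genes. Their interaction was not called (adjusted p = 0.103). At predawn the proteasome genes had a median of -0.03 with 1 lower, and their interaction was negative (adjusted p = 0.000147, but 0.33 with an estimated correlation).

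B-box zinc finger genes were higher in tic-2 at postdusk, with 10 of 19 higher and 2 lower (median 0.79, camera adjusted p = 1.27e-07, but 0.0806 with an estimated correlation), and the counts were the same after rescaling. At predawn 9 were higher and 6 lower, and the family was not called (adjusted p = 0.141). Their interaction was positive (median 0.22, adjusted p = 0.00577, but 0.299 with an estimated correlation).

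Other families were called as well, none of them with an estimated correlation. Pentatricopeptide genes were lower at predawn (50 of 216 lower and 3 higher, adjusted p = 7.27e-06, but 0.484 with an estimated correlation) and at postdusk (74 lower and 3 higher, 2e-05, but 0.332), where 26 were lower after rescaling. Higher at predawn were tubulin (15 higher and 4 lower of 28, 0.00759, but 0.484), arabinogalactan protein (12 and 3 of 37, 0.00759, but 0.632) and WRKY genes (11 and 2 of 40, 0.0177, but 0.632). At postdusk, cytochrome P450 (36 higher and 22 lower of 144, 0.00274, but 0.396) and aquaporin genes (4 and 0 of 27, 0.0164, but 0.332) were called as higher. Genes whose product names begin with the word histone were called as lower (2 and 33 of 91, 0.0171, but 0.332). That pattern is not limited to genes of the histones themselves. After rescaling the genes higher and lower were 37 and 14 for cytochrome P450, 9 and 0 for aquaporin and 6 and 17 for names beginning with histone. The interaction was positive for cytochrome P450 (0.000147, but 0.299) and negative for tubulin (0.000147, but 0.153) and calcium-binding or calmodulin genes (0.00522, but 0.299).

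The share of FPKM from organelle genes was 0.0758% in tic-2 postdusk C, against 0.126% to 0.214% in the other 11 libraries.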
